A study of Rattus norvegicus with 144 samples.

How the data were processed

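Livers of 72 male rats were compared on two-colour oligonucleotide arrays, 2 per rat. Per the labels, each rat's RNA was hybridised against a pool of RNA from 6 vehicle rats of the same time, with the dyes exchanged on the second array. Whether those were the vehicle rats measured here is not stated. The authors deposited processed values, assumed here to be log10 ratios of Cy5 over Cy3, and a key from rat number to dose. The log base, direction, background correction and dye normalization are not given in the sources used here. The median of every array as deposited lay between 0 and 0.000258, so the arrays may have been centred. Many exact zeros could also hold a median at 0. Centring each array on its median could therefore change next to nothing. Exact zeros made up 7.74% of the values and blanks 0.836%. A wrong base would scale all changes, and a dye effect that differed between arrays would add to the spread between rats.

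Rats were grouped by the time in the labels and the dose in the deposited key. No column of sample values was left out. Values were converted to log2, arrays with the rat's own RNA in Cy3 were turned in sign, and the 2 arrays of a rat were averaged, so that p-values are over rats. No 2 arrays held identical values. Arrays of the same dye orientation had no correlation below -0.3. Of 22075 probes, 12750 had 1 gene symbol, 5 had several and 9320 had none in the platform annotation. The Entrez gene of 12720 probes was found in a RefSeq gene table of assembly GRCr8, used for names alone, and 0 symbols were updated. Probes of 1 symbol were averaged, which concerned 2266 genes with more than 1 probe. Probes needed a value on at least 72 arrays, and 0 were dropped for this. Among the gene changes given in the text for which probes were compared, no probes of 1 gene differed in sign.

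Each comparison was a contrast of 12 group means fitted to all rats, with limma's moderated variances (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. Every adjusted p in the text is from limma, or from its camera test where named. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6. The fit was tested on simulated data for 24 h and 2000 mg/kg against vehicle over 18978 rows. It recovered 50% of genes changed by 0.5 on the log2 scale, 84% of those changed by 1 and 100% of those changed by 2. Of 171 calls, 12 were false. The simulation changed 200 rows and drew independent normal noise with the same SD per gene in all groups. It does not copy genes that move together or a group wider than the others. These rates therefore need not hold for the real comparison.

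Before the data were examined, 28 gene lists with 510 entries were fixed, of which 396 were measured. Each was tested with camera at a preset correlation of 0.01, two-sided, adjusted over all 252 tests. Of these 80 passed, 10 of them also with an estimated correlation, and 68 tests passed with fry, which asks whether a list's genes move one way on balance. The calls that held with an estimated correlation were NRF2 targets and cholesterol synthesis at 24 h (1500 and 2000 mg/kg), metal-responsive genes at 3 and 24 h (1500 and 2000 mg/kg), cholesterol synthesis at 6 h (1500 mg/kg) and stellate cell markers at 6 h (2000 mg/kg). Named genes followed a rule fixed at the same time. It took the 8 largest rises and 8 largest falls past the threshold with all dosed rats on the same side of the vehicle mean, and the 4 members of each list with the smallest p. For differences between doses or times it took 4 rises and 4 falls. Genes for checking the direction were named as well. Gclc was not used here.

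Alternatives were centring each array, either dye orientation alone, complete rows alone, 1 row per probe, all arrays with a dye term and the rat as a random block, the compared groups alone, quality weights per rat, a fold change of at least 1.5, and each rat left out in turn. Chosen after seeing the data were exact zeros as missing, a set of 49 arrays that share 500 blank probes as a covariate or split, and leaving out 12 rats whose 2 arrays correlated above -0.1 after the dye effect. That set held both arrays of 23 rats and 1 array of 3 rats, and 1161 rows were associated with it.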

Results

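Liver gene expression was measured in 72 male F344/N rats, an inbred laboratory strain, after acetaminophen, an analgesic that injures the liver in overdose. The comparisons ask how the response depends on dose and time. Rats received vehicle or 150, 1500 or 2000 mg/kg by gavage, and livers were taken at 3, 6 or 24 h, with 6 rats in each of 12 groups. RNA of each rat was hybridised on 2 arrays with the dyes exchanged, against a pool of RNA from vehicle rats of the same time. Of 22075 probes, 18978 gene rows were formed and tested. A row is a gene symbol, or a probe with no single symbol. The number of rats, with 2 arrays each, limits the precision.

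Doses came from the key deposited by the authors. The log base is not stated, and log10 was assumed. With another base every log2 value below would change by a common factor, while counts of changed genes at an adjusted p would stand. After removal of the mean dye effect, the 2 arrays of a rat correlated negatively in 63 of 72 rats (median -0.421, across probes, which are not independent replicates). This bears on the exchange of dyes and not on the direction of the ratio, which is likely and not certain. The direction rests on genes known to respond to the drug, which were higher at high doses. At 24 h and 2000 mg/kg the log2 difference from vehicle (± SE, here and below) was 3.93 ± 0.48 for metallothionein Mt2A and 2.85 ± 0.42 for Mt1. It was 2.43 ± 0.50 for heme oxygenase Hmox1, 2.16 ± 0.16 for the quinone reductase Nqo1 and 2.30 ± 0.20 for Gclm of glutathione synthesis. Each was above the vehicle mean in 6 of 6 rats, but Hmox1 of rat 9540 was at 0.16, below a vehicle rat at 0.33. Differences from vehicle and between doses compare 6 with 6 rats, and the SE uses 1 spread per gene shared by all 12 groups. For a group wider than the others the SE is therefore too small.

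At 150 mg/kg, Gsr, which reduces glutathione, differed from vehicle by 0.51 ± 0.23 and the aldehyde reductase Akr7a3 by 0.46 ± 0.22 at 3 h. Akr7a3 differed by 0.97 ± 0.22, adjusted p = 0.205 at 6 h, and Mt2A by -0.56 ± 0.48 at 24 h. None of these passed the threshold, but Akr7a3 at 6 h did with the rat as a random block, with quality weights per rat and with the shared blank probes as a covariate. With limma, 0 gene rows passed at each of the 3 times, and 708, 589 and 530 had an unadjusted p under 0.05 at 3, 6 and 24 h. Each count was below a share of 0.05 of the 18978 rows, which no effect would give on average. The median of the NRF2 targets, genes of antioxidant defence, was 0.14 (camera adjusted p = 0.000242, adjusted p = 0.389 with an estimated correlation) at 3 h. At 6 h it was 0.13 (camera adjusted p = 0.000313, adjusted p = 0.389 with an estimated correlation). The median of cholesterol synthesis genes was -0.15 (camera adjusted p = 1.89e-05, adjusted p = 0.178 with an estimated correlation) at 6 h. That of secreted hepatocyte proteins was 0.19 (camera adjusted p = 9.88e-09, adjusted p = 0.0938 with an estimated correlation) at 24 h. At 6 h the count was 2 without vehicle rat 1871 and 3 without 150 mg/kg rat 1277, and 1 without rat 5870. At 3 h it was 1 without rat 3426.

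**Figure D1:**
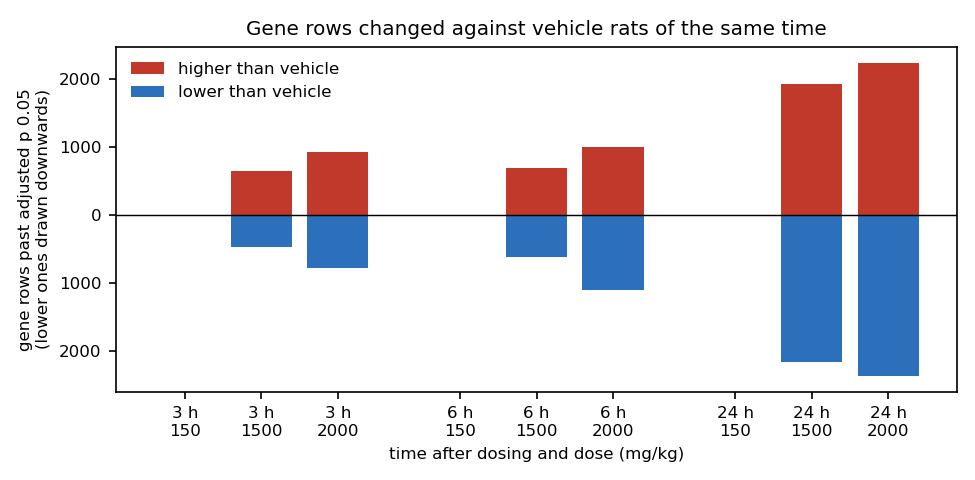
Number of gene rows past an adjusted p of 0.05 against vehicle rats (y axis, higher rows upwards, lower rows downwards) for each time and dose in mg/kg (x axis), 6 rats per group. Counts were 0 at 150 mg/kg and 4608 at 24 h and 2000 mg/kg.

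At 3 h, Slc38a2, an amino acid transporter, rose by 3.31 ± 0.40, adjusted p = 1.81e-08 at 1500 mg/kg and by 3.63 ± 0.40, adjusted p = 4.9e-10 at 2000 mg/kg. Igfbp1, which binds insulin-like growth factors, rose by 2.92 ± 0.52 and 3.28 ± 0.52 at the 2 doses, in that order here and below. Mt2A rose by 2.85 ± 0.48 and 3.18 ± 0.48, and Alas1, the first enzyme of heme synthesis, by 2.43 ± 0.33 and 2.84 ± 0.33. Rup2 fell, at -2.62 ± 0.46 at 1500 mg/kg. Dusp6, a phosphatase of MAP kinases, fell, at -2.41 ± 0.35 and -2.79 ± 0.35, and the hepatocyte transcription factor Foxa2 fell, at -2.09 ± 0.33 and -2.65 ± 0.33. The 3 genes were lower than the vehicle mean in 6 of 6 rats at each dose, a condition of the rule for naming the largest falls. In all, 1108 gene rows changed at 1500 mg/kg (644 higher, 464 lower), and 1710 gene rows changed at 2000 mg/kg (933 higher, 777 lower).

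At 3 h, of 12 gluconeogenesis and fasting genes, 5 rose and 0 fell at 1500 mg/kg (6 and 0 adjusted over the list alone), and 5 rose and 0 fell at 2000 mg/kg (5 and 0 adjusted over the list alone). Camera on gluconeogenesis and fasting genes gave adjusted p = 9.89e-05 at 1500 mg/kg (adjusted p = 0.0938 with an estimated correlation) and adjusted p = 0.000264 at 2000 mg/kg (adjusted p = 0.119 with an estimated correlation). Got1 (2.19 ± 0.29) and Sds (2.22 ± 0.38), which act on amino acids, rose at 1500 mg/kg. Of 3 metal-responsive genes, 2 rose and 0 fell at 1500 mg/kg (2 and 0 adjusted over the list alone), and 2 rose and 0 fell at 2000 mg/kg (2 and 0 adjusted over the list alone). Camera on metal-responsive genes gave adjusted p = 0.000814 at 1500 mg/kg (adjusted p = 0.0272 with an estimated correlation) and adjusted p = 0.000373 at 2000 mg/kg (adjusted p = 0.0204 with an estimated correlation). Of 14 immediate early genes, 4 rose and 1 fell at 2000 mg/kg (6 and 1 adjusted over the list alone). Camera on immediate early genes gave adjusted p = 0.00181 at 2000 mg/kg (adjusted p = 0.661 with an estimated correlation). Gadd45b was at 2.15 ± 0.42, Dusp1 at 1.72 ± 0.38 and Ier3 at -0.78 ± 0.22. Of 19 ER and integrated stress response genes, 4 rose and 0 fell at 2000 mg/kg (4 and 0 adjusted over the list alone). Camera on ER and integrated stress response genes gave adjusted p = 0.00174 at 2000 mg/kg (adjusted p = 0.496 with an estimated correlation). Herpud1, a protein of ER quality control, was at 1.37 ± 0.18. Of 15 p53 targets, 3 rose and 0 fell at 2000 mg/kg (4 and 2 adjusted over the list alone). Camera on p53 targets gave adjusted p = 0.082 at 2000 mg/kg (adjusted p = 0.679 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.45 ± 0.21, adjusted p = 7.37e-07. Of 24 NRF2 targets, 1 rose and 1 fell at 2000 mg/kg (1 and 1 adjusted over the list alone). Camera on NRF2 targets gave adjusted p = 0.662 at 2000 mg/kg (adjusted p = 0.989 with an estimated correlation). Osgin1 fell, at -1.86 ± 0.36, and the export pump Abcc3 rose by 0.74 ± 0.19. Of 9 stellate cell and fibroblast markers, 0 rose and 2 fell at 2000 mg/kg (0 and 2 adjusted over the list alone). Camera on stellate cell and fibroblast markers gave adjusted p = 0.522 at 2000 mg/kg (adjusted p = 0.766 with an estimated correlation). Their median was 0.04, the mean -0.07 and the test downward. Pdgfrb (-0.64 ± 0.16) and Rgs5 (-0.38 ± 0.09) fell.

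Some arrays shared 500 blank probes and were treated as a possible batch. Among rats without them, 476 and 871 rows changed at 3 h, and no vehicle rat of 3 h had them on both arrays. With them as a covariate the counts were 1111 and 1614.

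**Figure D2:**
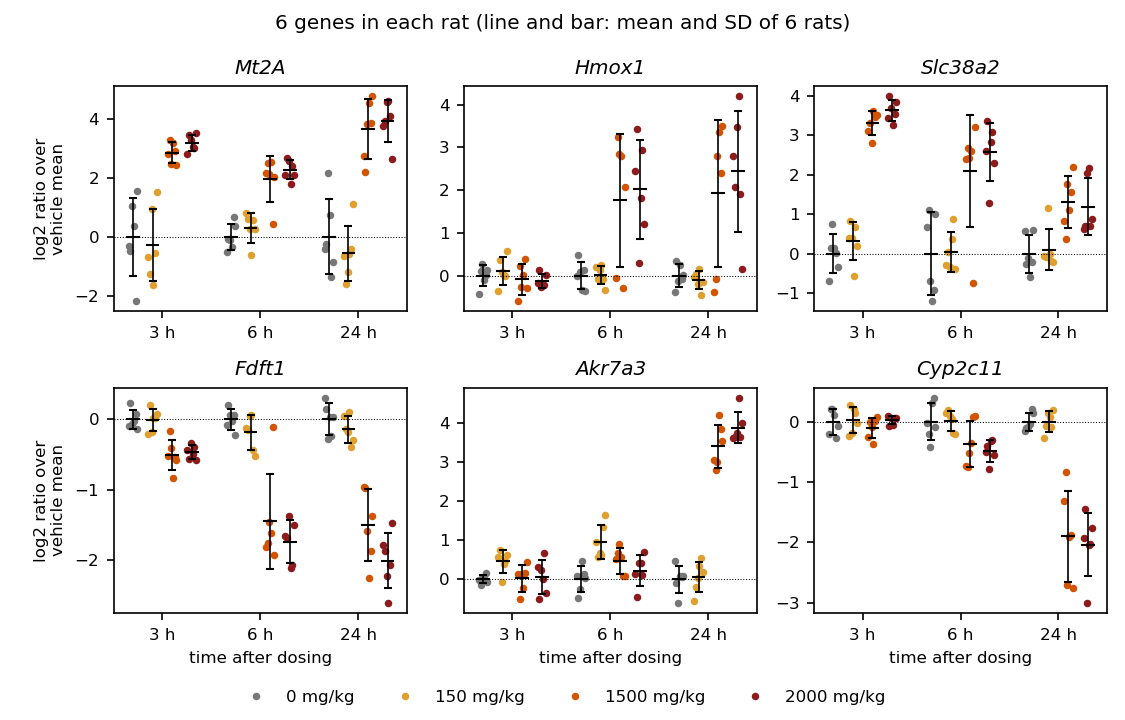
Log2 ratio of each rat over the mean of the vehicle rats of the same time (y axis) for 6 genes by time (x axis) and dose (colour), each point 1 rat, line and bar the mean and SD of 6 rats. Mt2A was at 0.42 or more in all rats given 1500 or 2000 mg/kg, but this does not separate them all from the other rats. The 0.42 was rat 7334 at 6 h and 1500 mg/kg, while rat 1045 at 6 h and 150 mg/kg was at 0.81. Vehicle rats reached 1.55 at 3 h, 0.67 at 6 h and 2.14 at 24 h. Hmox1 at 24 h and 1500 mg/kg ranged from -0.38 to 3.49.

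At 6 h, Cxcl1, a chemokine that attracts neutrophils, rose by 2.72 ± 0.65, adjusted p = 0.00384 at 1500 mg/kg and by 2.80 ± 0.65, adjusted p = 0.00171 at 2000 mg/kg. The early response factor Egr1 rose by 2.51 ± 0.65 and 2.58 ± 0.65, and Gadd45b by 2.29 ± 0.42 and 2.38 ± 0.42. The inducible heat shock protein Hspa1a rose by 2.65 ± 0.58 and 2.97 ± 0.58, the citrate transporter Slc13a5 by 2.16 ± 0.44 and 2.67 ± 0.44 and alkaline phosphatase Alpl by 2.29 ± 0.35 and 2.54 ± 0.35. Nrep fell, at -2.76 ± 0.44 and -3.15 ± 0.44, and Stac3 fell, at -2.28 ± 0.39 and -2.36 ± 0.39. In all, 1305 gene rows changed at 1500 mg/kg (692 higher, 613 lower), and 2115 gene rows changed at 2000 mg/kg (1007 higher, 1108 lower).

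At 6 h, of 19 cholesterol synthesis genes, 0 rose and 9 fell at 1500 mg/kg (0 and 14 adjusted over the list alone), and 0 rose and 9 fell at 2000 mg/kg (0 and 10 adjusted over the list alone). Camera on cholesterol synthesis genes gave adjusted p = 3.91e-12 at 1500 mg/kg (adjusted p = 0.0204 with an estimated correlation) and adjusted p = 5.16e-07 at 2000 mg/kg (adjusted p = 0.0938 with an estimated correlation). Fdft1, the first enzyme committed to sterols, was at -1.73 ± 0.18 and Msmo1 at -1.30 ± 0.24 at 2000 mg/kg. Of 13 fatty acid synthesis genes, 0 rose and 7 fell at 1500 mg/kg (0 and 7 adjusted over the list alone), and 0 rose and 4 fell at 2000 mg/kg (0 and 7 adjusted over the list alone). Camera on fatty acid synthesis genes gave adjusted p = 1.4e-06 at 1500 mg/kg (adjusted p = 0.139 with an estimated correlation) and adjusted p = 0.00189 at 2000 mg/kg (adjusted p = 0.47 with an estimated correlation). Acly (-1.38 ± 0.26) and Fasn (-1.31 ± 0.33) fell at 1500 mg/kg. Of 20 fatty acid oxidation genes, 3 rose and 0 fell at 2000 mg/kg (3 and 0 adjusted over the list alone). Camera on fatty acid oxidation genes gave adjusted p = 0.0355 at 2000 mg/kg (adjusted p = 0.861 with an estimated correlation). Carnitine acetyltransferase Crat was at 1.35 ± 0.21. Of 15 bile acid genes, 0 rose and 3 fell at 2000 mg/kg (1 and 5 adjusted over the list alone). Camera on bile acid genes gave adjusted p = 0.00131 at 2000 mg/kg (adjusted p = 0.511 with an estimated correlation). Amacr (-1.81 ± 0.21) and Baat (-1.76 ± 0.24), enzymes of bile acid synthesis and conjugation, fell. Of 14 immediate early genes, 8 rose and 0 fell at 1500 mg/kg (12 and 0 adjusted over the list alone), and 7 rose and 0 fell at 2000 mg/kg (12 and 0 adjusted over the list alone). Camera on immediate early genes gave adjusted p = 7.37e-11 at 1500 mg/kg (adjusted p = 0.105 with an estimated correlation) and adjusted p = 3.28e-08 at 2000 mg/kg (adjusted p = 0.204 with an estimated correlation). Of 24 NRF2 targets, 6 rose and 1 fell at 2000 mg/kg (7 and 1 adjusted over the list alone). Camera on NRF2 targets gave adjusted p = 0.0355 at 2000 mg/kg (adjusted p = 0.73 with an estimated correlation). Hmox1 rose by 2.02 ± 0.50, adjusted p = 0.00331 and Osgin1 by 1.35 ± 0.36, adjusted p = 0.00674. Hmox1 of rat 6930 was at 0.29, below a vehicle rat at 0.48. Of 22 urea cycle and amino acid genes, 7 rose and 2 fell at 2000 mg/kg (8 and 2 adjusted over the list alone). Camera on urea cycle and amino acid genes gave adjusted p = 0.00314 at 2000 mg/kg (adjusted p = 0.692 with an estimated correlation). Tdo2, which breaks down tryptophan, was at 1.24 ± 0.18. Of 9 stellate cell and fibroblast markers, 0 rose and 4 fell at 2000 mg/kg (0 and 5 adjusted over the list alone). Camera on stellate cell and fibroblast markers gave adjusted p = 0.00372 at 2000 mg/kg (adjusted p = 0.0328 with an estimated correlation). Pdgfrb was at -1.09 ± 0.16 and Col1a2 at -0.46 ± 0.15.

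Without rat 7334, 2034 rows changed at 6 h and 1500 mg/kg in place of 1305. Among rats without the shared blank probes, 299 rows changed at 1500 mg/kg and 501 at 2000 mg/kg, and among rats with them 1137 at 2000 mg/kg. Only 1 rat of 6 h and 1500 mg/kg had them on both arrays, so no count is given for it here. With the compared groups alone in the fit, 770 rows changed at 1500 mg/kg.

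At 24 h, Akr7a3 rose by 3.41 ± 0.22, adjusted p = 3.67e-19 at 1500 mg/kg (10.7-fold) and by 3.88 ± 0.22, adjusted p = 3.7e-22 at 2000 mg/kg (14.8-fold), in 6 of 6 rats each. The rule for naming the largest rises required this. The acute phase protein A2m rose by 4.41 ± 0.53 and 3.88 ± 0.53, Hspa1a by 3.39 ± 0.58 and 4.02 ± 0.58 and the stress pseudokinase Trib3 by 3.02 ± 0.34 and 3.60 ± 0.34. Stac3 fell, at -4.02 ± 0.39 and -4.72 ± 0.39, and Nrep fell, at -3.42 ± 0.44 and -3.96 ± 0.44. The carbonic anhydrase Car7 fell, at -3.04 ± 0.33 and -3.50 ± 0.33, and the drug-metabolising cytochrome Cyp3a2 fell, at -2.28 ± 0.37 and -2.76 ± 0.37. In all, 4083 gene rows changed at 1500 mg/kg (1927 higher, 2156 lower), and 4608 gene rows changed at 2000 mg/kg (2242 higher, 2366 lower).

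At 24 h, of 24 NRF2 targets, 18 rose and 0 fell at 1500 mg/kg (19 and 0 adjusted over the list alone), and 23 rose and 0 fell at 2000 mg/kg (24 and 0 adjusted over the list alone). Camera on NRF2 targets gave adjusted p = 1.13e-18 at 1500 mg/kg (adjusted p = 0.00671 with an estimated correlation) and adjusted p = 5.54e-24 at 2000 mg/kg (adjusted p = 0.00119 with an estimated correlation). The glutathione transferase Gstp1 rose by 1.46 ± 0.21 at 1500 mg/kg and ferritin light chain Ftl1 by 1.48 ± 0.16 at 2000 mg/kg. Of 14 heat shock proteins, 14 rose and 0 fell at 1500 mg/kg (14 and 0 adjusted over the list alone), and 13 rose and 0 fell at 2000 mg/kg (14 and 0 adjusted over the list alone). Camera on heat shock proteins gave adjusted p = 5.16e-15 at 1500 mg/kg (adjusted p = 0.0938 with an estimated correlation) and adjusted p = 1.16e-17 at 2000 mg/kg (adjusted p = 0.0616 with an estimated correlation). Hsp90aa1 was at 2.38 ± 0.27 and Hspa8 at 1.79 ± 0.21. Of 19 ER and integrated stress response genes, 14 rose and 0 fell at 1500 mg/kg (17 and 0 adjusted over the list alone), and 15 rose and 0 fell at 2000 mg/kg (15 and 0 adjusted over the list alone). Camera on ER and integrated stress response genes gave adjusted p = 1.22e-10 at 1500 mg/kg (adjusted p = 0.0616 with an estimated correlation) and adjusted p = 1.92e-08 at 2000 mg/kg (adjusted p = 0.0938 with an estimated correlation). Asns was at 1.63 ± 0.24 and the hormone Fgf21 at 1.75 ± 0.29. Of 14 immediate early genes, 12 rose and 0 fell at 2000 mg/kg (13 and 0 adjusted over the list alone). Camera on immediate early genes gave adjusted p = 4.99e-07 at 2000 mg/kg (adjusted p = 0.286 with an estimated correlation). Myc was at 2.52 ± 0.40 and Atf3 at 3.65 ± 0.65. Of 3 metal-responsive genes, 3 rose and 0 fell at 1500 mg/kg (3 and 0 adjusted over the list alone), and 3 rose and 0 fell at 2000 mg/kg (3 and 0 adjusted over the list alone). Camera on metal-responsive genes gave adjusted p = 0.000706 at 1500 mg/kg (adjusted p = 0.0272 with an estimated correlation) and adjusted p = 0.00124 at 2000 mg/kg (adjusted p = 0.0328 with an estimated correlation). Of 15 p53 targets, 6 rose and 0 fell at 2000 mg/kg (8 and 1 adjusted over the list alone). Camera on p53 targets gave adjusted p = 0.00626 at 2000 mg/kg (adjusted p = 0.386 with an estimated correlation). Mdm2, which restrains p53, was at 0.71 ± 0.17. Of 15 acute phase proteins, 9 rose and 1 fell at 1500 mg/kg (10 and 1 adjusted over the list alone), and 8 rose and 1 fell at 2000 mg/kg (8 and 1 adjusted over the list alone). Camera on acute phase proteins gave adjusted p = 0.000117 at 1500 mg/kg (adjusted p = 0.389 with an estimated correlation) and adjusted p = 0.0195 at 2000 mg/kg (adjusted p = 0.717 with an estimated correlation). Orm1 was at 1.37 ± 0.21 at 1500 mg/kg, and Crp, which fell, at -0.64 ± 0.17 at 2000 mg/kg.

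Markers of other liver cells were measured beside these stress genes at 24 h. Of 17 cytokine, chemokine and NF-kB genes, 7 rose and 0 fell at 1500 mg/kg (9 and 0 adjusted over the list alone). Camera on cytokine, chemokine and NF-kB genes gave adjusted p = 0.00624 at 1500 mg/kg (adjusted p = 0.609 with an estimated correlation). The chemokine Ccl2 was at 2.52 ± 0.74, higher in 4 of 6 rats. Of 7 neutrophil markers, 3 rose and 0 fell at 1500 mg/kg (3 and 0 adjusted over the list alone). Camera on neutrophil markers gave adjusted p = 0.189 at 1500 mg/kg (adjusted p = 0.717 with an estimated correlation). S100a9 was at 2.20 ± 0.54, but the 6 rats were uneven. Their values ranged from 0.08 in rat 9398 to 5.03 in rat 9537, with 0.33 in rat 5389 and 4.49 in rat 7075. Of 11 macrophage and Kupffer cell markers, 0 rose and 4 fell at 2000 mg/kg (0 and 4 adjusted over the list alone). Camera on macrophage and Kupffer cell markers gave adjusted p = 0.0287 at 2000 mg/kg (adjusted p = 0.496 with an estimated correlation). Clec4f was at -0.91 ± 0.14 and Cd5l at -0.79 ± 0.13. Of 14 lymphocyte markers, 0 rose and 4 fell at 1500 mg/kg (0 and 4 adjusted over the list alone). Camera on lymphocyte markers gave adjusted p = 0.23 at 1500 mg/kg (adjusted p = 0.722 with an estimated correlation). Lck was at -0.69 ± 0.16. Of 9 stellate cell and fibroblast markers, 0 rose and 3 fell at 2000 mg/kg (0 and 3 adjusted over the list alone). Camera on stellate cell and fibroblast markers gave adjusted p = 0.0555 at 2000 mg/kg (adjusted p = 0.189 with an estimated correlation). Lrat, which stores retinoids, was at -1.73 ± 0.21. Of 9 endothelial markers, 0 rose and 4 fell at 2000 mg/kg (0 and 4 adjusted over the list alone). Camera on endothelial markers gave adjusted p = 0.0212 at 2000 mg/kg (adjusted p = 0.119 with an estimated correlation). Vwf was at -0.46 ± 0.08. Of 24 cell cycle genes, 1 rose and 11 fell at 1500 mg/kg (3 and 14 adjusted over the list alone). Camera on cell cycle genes gave adjusted p = 0.00236 at 1500 mg/kg (adjusted p = 0.558 with an estimated correlation). Birc5 was at -1.15 ± 0.19 and Cdk1 at -1.82 ± 0.33.

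Also at 24 h, of 19 cholesterol synthesis genes, 0 rose and 16 fell at 1500 mg/kg (0 and 16 adjusted over the list alone), and 0 rose and 17 fell at 2000 mg/kg (0 and 18 adjusted over the list alone). Camera on cholesterol synthesis genes gave adjusted p = 2.84e-21 at 1500 mg/kg (adjusted p = 0.000766 with an estimated correlation) and adjusted p = 9.86e-25 at 2000 mg/kg (adjusted p = 0.000306 with an estimated correlation). Cyp51 fell, at -1.77 ± 0.14 and -2.27 ± 0.14. Of 13 fatty acid synthesis genes, 0 rose and 10 fell at 1500 mg/kg (0 and 10 adjusted over the list alone), and 1 rose and 10 fell at 2000 mg/kg (1 and 10 adjusted over the list alone). Camera on fatty acid synthesis genes gave adjusted p = 3.1e-09 at 1500 mg/kg (adjusted p = 0.0626 with an estimated correlation) and adjusted p = 2.63e-06 at 2000 mg/kg (adjusted p = 0.157 with an estimated correlation). The desaturase Fads1 fell, at -2.80 ± 0.26 and -3.31 ± 0.26. Of 20 fatty acid oxidation genes, 2 rose and 3 fell at 1500 mg/kg (2 and 3 adjusted over the list alone). Camera on fatty acid oxidation genes gave adjusted p = 0.74 at 1500 mg/kg (adjusted p = 1 with an estimated correlation). Acadm was at -0.88 ± 0.15 and Acaa2 at 0.54 ± 0.12. Of 20 cytochrome P450 genes, 1 rose and 12 fell at 1500 mg/kg (2 and 12 adjusted over the list alone), and 1 rose and 12 fell at 2000 mg/kg (3 and 12 adjusted over the list alone). Camera on cytochrome P450 genes gave adjusted p = 0.000104 at 1500 mg/kg (adjusted p = 0.379 with an estimated correlation) and adjusted p = 3.8e-05 at 2000 mg/kg (adjusted p = 0.318 with an estimated correlation). Cyp2c11, expressed mainly in males, fell, at -1.90 ± 0.19 and -2.03 ± 0.19. Of 18 conjugation genes, 7 rose and 5 fell at 1500 mg/kg (7 and 5 adjusted over the list alone). Camera on conjugation genes gave adjusted p = 0.23 at 1500 mg/kg (adjusted p = 0.914 with an estimated correlation). Their median was -0.09, the mean 0.10 and the test upward. Gsta3 was at 1.46 ± 0.20 and Sult1c3 at -1.71 ± 0.26. Of 15 bile acid genes, 0 rose and 12 fell at 1500 mg/kg (1 and 12 adjusted over the list alone), and 1 rose and 11 fell at 2000 mg/kg (2 and 12 adjusted over the list alone). Camera on bile acid genes gave adjusted p = 2.42e-06 at 1500 mg/kg (adjusted p = 0.228 with an estimated correlation) and adjusted p = 5.98e-05 at 2000 mg/kg (adjusted p = 0.379 with an estimated correlation). Slc27a5 was at -1.33 ± 0.19 and the transporter Slco1a1 at -1.22 ± 0.19.

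At 24 h, of 22 urea cycle and amino acid genes, 1 rose and 13 fell at 1500 mg/kg (1 and 13 adjusted over the list alone), and 1 rose and 8 fell at 2000 mg/kg (2 and 10 adjusted over the list alone). Camera on urea cycle and amino acid genes gave adjusted p = 1.72e-05 at 1500 mg/kg (adjusted p = 0.408 with an estimated correlation) and adjusted p = 0.0207 at 2000 mg/kg (adjusted p = 0.785 with an estimated correlation). Otc was at -1.28 ± 0.16 and Oat at -1.83 ± 0.19. Of 12 gluconeogenesis and fasting genes, 1 rose and 3 fell at 2000 mg/kg (3 and 5 adjusted over the list alone). Camera on gluconeogenesis and fasting genes gave adjusted p = 0.979 at 2000 mg/kg (adjusted p = 1 with an estimated correlation). Their median was 0.08, the mean 0.10 and the test downward. Of 20 secreted hepatocyte proteins, 0 rose and 7 fell at 2000 mg/kg (0 and 7 adjusted over the list alone). Camera on secreted hepatocyte proteins gave adjusted p = 0.0237 at 2000 mg/kg (adjusted p = 0.717 with an estimated correlation). Apoa2 was at -0.71 ± 0.10 and Igf1 at -0.63 ± 0.10. Of 10 pericentral hepatocyte genes, 0 rose and 6 fell at 1500 mg/kg (0 and 6 adjusted over the list alone), and 0 rose and 6 fell at 2000 mg/kg (1 and 6 adjusted over the list alone). Camera on pericentral hepatocyte genes gave adjusted p = 1.04e-05 at 1500 mg/kg (adjusted p = 0.0667 with an estimated correlation) and adjusted p = 5.78e-05 at 2000 mg/kg (adjusted p = 0.0938 with an estimated correlation). Glutamine synthetase Glul fell, at -1.70 ± 0.16 and -1.99 ± 0.16. Of 11 periportal hepatocyte genes, 1 rose and 7 fell at 1500 mg/kg (1 and 8 adjusted over the list alone). Camera on periportal hepatocyte genes gave adjusted p = 0.00324 at 1500 mg/kg (adjusted p = 0.389 with an estimated correlation). Ctsc was at -0.91 ± 0.11 and the urea cycle enzyme Arg1 at 0.49 ± 0.12.

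Among rats without and with the shared blank probes at 24 h, 594 and 3514 rows changed at 1500 mg/kg and 2772 and 2360 at 2000 mg/kg. Each split set 3 dosed against 4 vehicle rats without them and 3 against 2 with them. At 1500 mg/kg Hmox1 was at -0.38, -0.08 and 2.79 in rats 0504, 5389 and 7075 without them. In the rats with them it was at 2.40 to 3.49. The counts at 1500 mg/kg therefore cannot tell an effect of the arrays from a difference between rats. With the compared groups alone in the fit, 1406 changed at 1500 mg/kg.

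**Figure D3:**
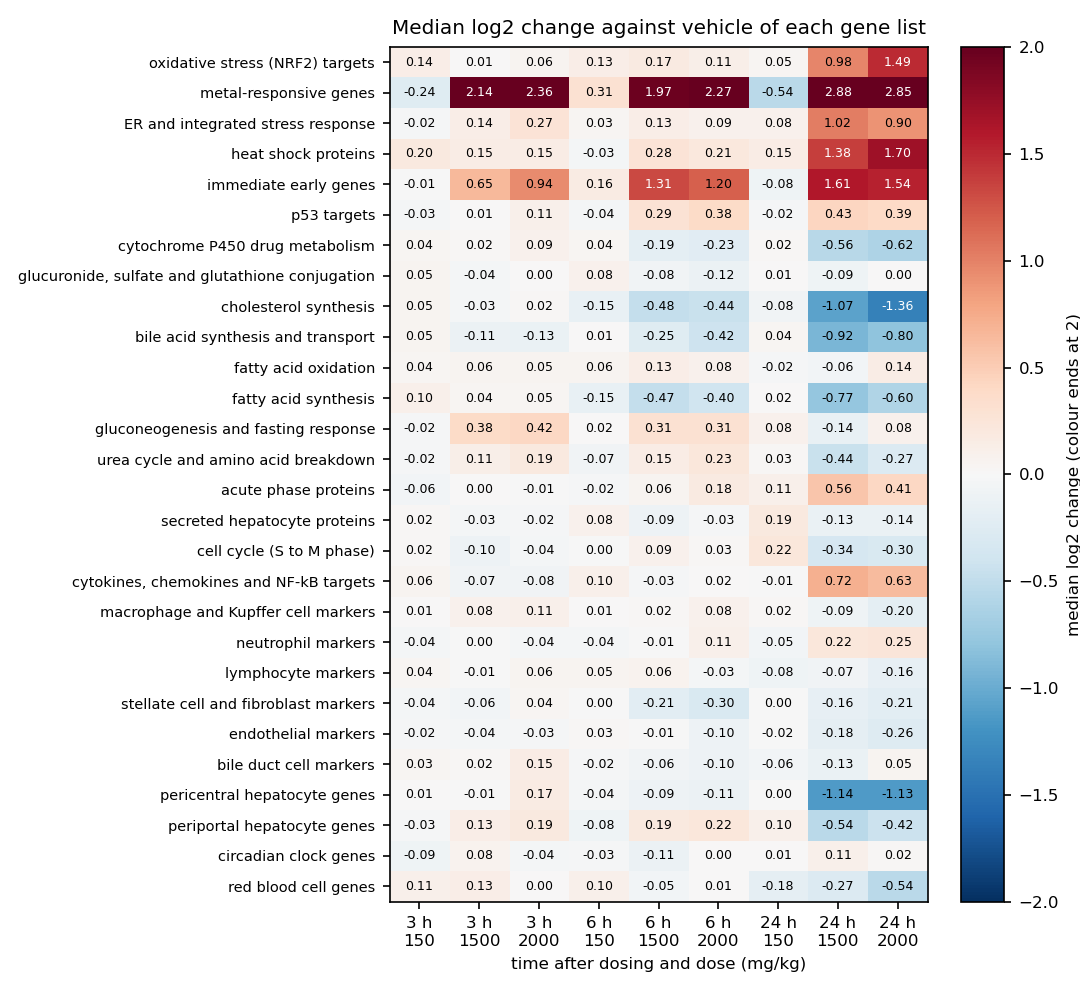
Median log2 change against vehicle over the measured members of 28 gene lists (rows) by time and dose in mg/kg (columns), red higher and blue lower, with colours ending at 2. At 24 h and 2000 mg/kg the median was 1.70 for heat shock proteins and -1.36 for cholesterol synthesis.

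Mt2A was higher at 1500 than at 150 mg/kg by 3.12 ± 0.48, adjusted p = 3.81e-06 at 3 h and by 4.21 ± 0.48, adjusted p = 8.45e-10 at 24 h. Hspa1a was higher by 2.85 ± 0.58, adjusted p = 0.000582 at 6 h. Foxa2 was lower at 3 h, with a difference of -2.21 ± 0.33, and Fads1 at 24 h, with -2.93 ± 0.26. At 24 h 18 of 24 NRF2 targets and 14 of 14 heat shock proteins were higher, and 15 of 19 cholesterol synthesis genes lower. In all, 793 gene rows differed at 3 h, 1001 at 6 h and 3704 at 24 h. Among rats without the shared blank probes the counts were 418, 372 and 487, and among rats with them 3447 at 24 h. The 24 h rats without them given 1500 mg/kg included 0504 and 5389, with Hmox1 at -0.38 and -0.08. At 6 h only 1 rat given 1500 mg/kg had them on both arrays, so no count is given here. At 6 h the count was 1662 without rat 7334 and 597 without rat 8918, and with the compared groups alone in the fit it was 232 at 6 h and 1604 at 24 h.

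Between 2000 and 1500 mg/kg at 24 h, Hmox1 differed by 0.51 (95% interval -0.49 to 1.51, adjusted p = 1) and Mt2A by 0.28 (95% interval -0.69 to 1.24, adjusted p = 1). Akr7a3 differed by 0.47 (95% interval 0.04 to 0.90, adjusted p = 1). Cyp51 differed by -0.50 (95% interval -0.77 to -0.23, adjusted p = 0.935) and Cyp2c11 by -0.13 (95% interval -0.51 to 0.24, adjusted p = 1). Without adjustment for the number of rows, the intervals of Hmox1, Mt2A and Cyp2c11 include 0 and those of Akr7a3 and Cyp51 do not. With limma, 2, 1 and 0 gene rows passed at 3, 6 and 24 h, and 792, 772 and 845 had an unadjusted p under 0.05. The latter counts were below a share of 0.05 of the 18978 rows, which no effect would give on average. The rows that passed had no gene symbol here. At 6 h the count was 0 without any of rats 0644, 1550, 2123, 5407, 5886, 6930, 7334, 8918, and at 3 h it was 3 without rat 7515 or 8596. Among rats without the shared blank probes 5, 2 and 6 rows passed at 3, 6 and 24 h, and among rats with them 0 at 24 h. At 3 h and at 6 h only 1 rat given 1500 mg/kg had them on both arrays, so no count is given here.

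From 3 to 6 h the response of Osgin1 rose by 2.91 ± 0.51, adjusted p = 0.000384 at 1500 mg/kg and by 3.21 ± 0.51, adjusted p = 2.25e-05 at 2000 mg/kg. That of Insig1, which restrains sterol synthesis, fell, at -2.70 ± 0.49 and -2.71 ± 0.49, and that of the nuclear receptor Nr0b2 fell, at -2.65 ± 0.64 and -2.82 ± 0.64. The response of the cytokine Il10 fell at 2000 mg/kg, at -3.37 ± 0.57. From 6 to 24 h the response of Akr7a3 rose by 2.94 ± 0.30 and 3.67 ± 0.30 and that of the export pump Abcb1a by 2.56 ± 0.50 and 4.11 ± 0.50. That of Aspa fell, at -3.01 ± 0.42 and -3.40 ± 0.42. At 2000 mg/kg 16 of 24 NRF2 targets and 12 of 14 heat shock proteins had a higher response at 24 h than at 6 h. A lower one was found for 11 of 19 cholesterol synthesis genes and 10 of 22 urea cycle and amino acid genes. In all, the response differed in 165 and 656 gene rows from 3 to 6 h and in 1805 and 2464 from 6 to 24 h. From 3 to 6 h at 1500 mg/kg the count was 417 without rat 7334. Among rats without the shared blank probes, the counts were 31 and 197 from 3 to 6 h and 66 and 787 from 6 to 24 h. Among rats with them the count was 850 from 6 to 24 h at 2000 mg/kg. At 1500 mg/kg only 1 rat of 6 h had them on both arrays, so no count is given here. With the compared groups alone in the fit, the count was 986 from 3 to 6 h at 2000 mg/kg and 743 from 6 to 24 h at 1500 mg/kg.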

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

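All tests on rat 7334 were chosen after its values were seen. For each gene list and group, the mean log2 value of each rat over the vehicle mean was set against the other 5 rats. In 26 of 336 groups 1 rat lay apart by Dixon's test, where chance gives about 1 in 20, or 16.8.

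Rat 7334 (6 h, 1500 mg/kg) was at 0.03 for bile acid synthesis and transport (others -0.60 to -0.43) and -0.19 for cholesterol synthesis (others -0.58 to -0.53), and at 0.35 for lymphocyte markers (others -0.11 to 0.05) and -0.03 for stellate cell and fibroblast markers (others -0.28 to -0.20). Over 293 genes changed at least 2-fold in the other 5 rats, its changes had a slope of 0.0215 on theirs. The slope was 0.856 to 1.09 in those rats, in which the genes were chosen, and 0.65 to 1.09 in rats given 2000 mg/kg. In vehicle and 150 mg/kg rats it was -0.105 to 0.136. The 2 arrays of rat 7334 mirrored each other, with a correlation of -0.49, which argues against poor arrays. The highest slope of 0.136 among vehicle and 150 mg/kg rats argues against a swap with them. A wrong rat number with no partner may account for the slope of 0.0215. Poor uptake of the dose cannot be told apart from it, because an undosed rat would also have a slope near 0, and its Atf3 of 2.32, above the 1.43 or less of vehicle and 150 mg/kg rats of 6 h, is 1 gene and decides neither.

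Rat 0186 (3 h, 1500 mg/kg) was at -0.21 for pericentral hepatocyte genes (others 0.03 to 0.13). Rat 0613 (3 h, 150 mg/kg) was at -0.22 for secreted hepatocyte proteins (others 0.00 to 0.09). Rat 0685 (24 h, vehicle) was at -0.12 for fatty acid oxidation (others -0.01 to 0.05) and 0.19 for conjugation (others -0.07 to 0.01). For rat 0685 it was -0.21 for pericentral hepatocyte genes (others -0.01 to 0.10) and -0.23 for secreted hepatocyte proteins (others 0.00 to 0.09). Rat 1009 (3 h, vehicle) was at -0.41 for periportal hepatocyte genes (others 0.00 to 0.16). Rat 1049 (3 h, 150 mg/kg) was at 0.06 for stellate cell and fibroblast markers (others -0.09 to -0.06). Rat 1457 (24 h, vehicle) was at 0.16 for endothelial markers (others -0.06 to 0.02). Rat 1550 (6 h, 2000 mg/kg) was at 0.19 for bile duct cell markers (others -0.23 to -0.11) and 0.03 for cytokines, chemokines and NF-kB targets (others 0.15 to 0.22). Rat 2698 (3 h, vehicle) was at -0.35 for cytokines, chemokines and NF-kB targets (others -0.01 to 0.10). Rat 4550 (6 h, vehicle) was at -0.15 for conjugation (others -0.01 to 0.07). Rat 4623 (3 h, 1500 mg/kg) was at 0.16 for secreted hepatocyte proteins (others -0.15 to -0.05). Rat 4678 (24 h, 150 mg/kg) was at -0.29 for red blood cell genes (others -0.17 to -0.10). Rat 5407 (6 h, 1500 mg/kg) was at 0.22 for endothelial markers (others 0.00 to 0.04). Rat 5557 (3 h, vehicle) was at 0.35 for cell cycle (others -0.12 to 0.03). Rat 5889 (24 h, 2000 mg/kg) was at 1.15 for bile duct cell markers (others -0.39 to -0.04) and 1.65 for neutrophil markers (others 0.03 to 0.63). Rat 7198 (24 h, 150 mg/kg) was at 0.12 for NRF2 targets (others 0.01 to 0.04). Rat 7365 (3 h, 2000 mg/kg) was at -0.21 for circadian clock genes (others 0.03 to 0.14) and 0.49 for pericentral hepatocyte genes (others 0.03 to 0.16).

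The response to a dose differed between times, by a test of the difference, in 165 and 656 gene rows from 3 to 6 h and in 1805 and 2464 from 6 to 24 h, at 1500 and 2000 mg/kg. Of 100 splits of the same rats, the real one included, 1, 3, 1 and 2 gave as many rows. The splits exchanged dosed and vehicle rats within a time, which removes the dose effect itself. They therefore cannot decide whether chance made the responses of 2 times differ. The highest others gave 14, 1051, 1501 and 2768.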

How the results depend on the processing

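Exact zeros as missing, the shared blank probes as covariate or split, and leaving out rats whose arrays did not mirror each other were chosen after seeing the data. No paired analysis was possible because the groups hold different rats and share no rat numbers. Counts given here lay more than 1.5 times from the reported ones, and the cause was not tested, except that a fold minimum lowers a count by construction. Arrays with own RNA in Cy5 alone gave 686 for 1500 mg/kg at 3 h and 0 for 2000 against 1500 mg/kg at 6 h. Arrays with own RNA in Cy3 alone gave 1113 for 2000 mg/kg at 3 h, 0 for 2000 against 1500 mg/kg at 6 h and 1171 for 1500 mg/kg from 6 to 24 h. For in Cy3 alone, more counts were 320 for 2000 mg/kg from 3 to 6 h. Only rows with values on all arrays gave 1 for 2000 against 1500 mg/kg at 3 h. Exact zeros taken as missing gave 0 for 2000 against 1500 mg/kg at 6 h. 1 row per probe gave 0 for 2000 against 1500 mg/kg at 6 h. All arrays with the rat as a random block gave 3 for 150 mg/kg at 6 h, 2221 for 1500 mg/kg at 6 h and 1268 for 1500 against 150 mg/kg at 3 h. For a random block, more counts were 18 for 2000 against 1500 mg/kg at 3 h, 1851 for 1500 against 150 mg/kg at 6 h and 0 for 2000 against 1500 mg/kg at 6 h. They were also 10 for 2000 against 1500 mg/kg at 24 h, 656 for 1500 mg/kg from 3 to 6 h and 2739 for 1500 mg/kg from 6 to 24 h. For a random block, more counts were 1306 for 2000 mg/kg from 3 to 6 h. The compared groups alone in the fit gave 3 for 150 mg/kg at 6 h, 770 for 1500 mg/kg at 6 h and 1406 for 1500 mg/kg at 24 h. For in the fit, more counts were 0 for 2000 against 1500 mg/kg at 3 h, 232 for 1500 against 150 mg/kg at 6 h and 0 for 2000 against 1500 mg/kg at 6 h. They were also 1604 for 1500 against 150 mg/kg at 24 h, 743 for 1500 mg/kg from 6 to 24 h and 986 for 2000 mg/kg from 3 to 6 h. Quality weights per rat gave 1663 for 1500 mg/kg at 3 h, 5 for 150 mg/kg at 6 h and 3094 for 1500 mg/kg at 6 h. For weights per rat, more counts were 4260 for 2000 mg/kg at 6 h, 1938 for 1500 against 150 mg/kg at 3 h and 23 for 2000 against 1500 mg/kg at 3 h. They were also 2414 for 1500 against 150 mg/kg at 6 h, 0 for 2000 against 1500 mg/kg at 6 h and 787 for 1500 mg/kg from 3 to 6 h. For weights per rat, more counts were 2846 for 1500 mg/kg from 6 to 24 h and 1266 for 2000 mg/kg from 3 to 6 h. A 1.5-fold minimum as well gave 546 for 1500 mg/kg at 3 h, 833 for 2000 mg/kg at 3 h and 543 for 1500 mg/kg at 6 h. For minimum as well, more counts were 850 for 2000 mg/kg at 6 h, 1638 for 1500 mg/kg at 24 h and 1905 for 2000 mg/kg at 24 h. They were also 428 for 1500 against 150 mg/kg at 3 h, 434 for 1500 against 150 mg/kg at 6 h and 0 for 2000 against 1500 mg/kg at 6 h. For minimum as well, more counts were 1563 for 1500 against 150 mg/kg at 24 h, 1093 for 1500 mg/kg from 6 to 24 h and 435 for 2000 mg/kg from 3 to 6 h. They were also 1525 for 2000 mg/kg from 6 to 24 h. Arrays with the shared blank probes as a covariate gave 2 for 150 mg/kg at 6 h. Rats without the shared blank probes gave 476 for 1500 mg/kg at 3 h, 871 for 2000 mg/kg at 3 h and 299 for 1500 mg/kg at 6 h. For shared blank probes, more counts were 501 for 2000 mg/kg at 6 h, 594 for 1500 mg/kg at 24 h and 2772 for 2000 mg/kg at 24 h. They were also 418 for 1500 against 150 mg/kg at 3 h, 5 for 2000 against 1500 mg/kg at 3 h and 372 for 1500 against 150 mg/kg at 6 h. For shared blank probes, more counts were 2 for 2000 against 1500 mg/kg at 6 h, 487 for 1500 against 150 mg/kg at 24 h and 6 for 2000 against 1500 mg/kg at 24 h. They were also 31 for 1500 mg/kg from 3 to 6 h, 66 for 1500 mg/kg from 6 to 24 h and 197 for 2000 mg/kg from 3 to 6 h. For shared blank probes, more counts were 787 for 2000 mg/kg from 6 to 24 h. Rats with the shared blank probes on both arrays gave 401 for 1500 mg/kg at 6 h, 1137 for 2000 mg/kg at 6 h and 2360 for 2000 mg/kg at 24 h. For on both arrays, more counts were 5 for 2000 against 1500 mg/kg at 3 h, 237 for 1500 against 150 mg/kg at 6 h and 13 for 2000 against 1500 mg/kg at 6 h. They were also 693 for 1500 mg/kg from 6 to 24 h and 850 for 2000 mg/kg from 6 to 24 h. With the shared blank probes on both arrays, each count using 1500 mg/kg at 3 or 6 h has only 1 rat in that group. Such a count has no replicate there, and nothing is concluded from it. Leaving out the rats whose arrays did not mirror each other gave 3 for 150 mg/kg at 3 h, 666 for 2000 mg/kg at 3 h and 1 for 150 mg/kg at 6 h. For mirror each other, more counts were 1317 for 2000 mg/kg at 6 h, 1 for 2000 against 1500 mg/kg at 3 h and 0 for 2000 against 1500 mg/kg at 6 h. They were also 69 for 1500 mg/kg from 3 to 6 h, 1137 for 1500 mg/kg from 6 to 24 h and 155 for 2000 mg/kg from 3 to 6 h. Leaving out each rat in turn gave 0 to 1 for 150 mg/kg at 3 h, 0 to 3 for 150 mg/kg at 6 h, 912 to 2034 for 1500 mg/kg at 6 h. For others it gave 597 to 1662 for 1500 against 150 mg/kg at 6 h, 0 to 1 for 2000 against 1500 mg/kg at 6 h, 116 to 417 for 1500 mg/kg from 3 to 6 h. Of the values of single genes under these settings, 3386 kept their direction and side of the threshold, 81 kept their direction and missed it, 3 kept it and came to pass, each of them Akr7a3 at 6 h and 150 mg/kg, and 0 reversed. Of 252 list tests, 70 lost their call with an estimated correlation, and with fry 25 lost and 13 gained one. Centring each array changed none, but array medians already lay between 0 and 0.000258, so this was all but fixed beforehand. The same holds for the centred values of single genes counted above. Signal over background was not used here.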

Other observations

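The pairing of arrays between rats was tested only after the result was seen, and Hmox1, Atf3 and Hspa1a were chosen after their values were seen. At 3 h, of 10 circadian clock genes, 2 rose and 1 fell at 2000 mg/kg (3 and 1 adjusted over the list alone). Camera on circadian clock genes gave adjusted p = 0.817 at 2000 mg/kg (adjusted p = 0.984 with an estimated correlation). The clock repressor Per2 was at -1.41 ± 0.32 and Nfil3 at 0.54 ± 0.12. At 24 h, of 3 red blood cell genes, 0 rose and 2 fell at 2000 mg/kg (0 and 3 adjusted over the list alone). Camera on red blood cell genes gave adjusted p = 0.0667 at 2000 mg/kg (adjusted p = 0.389 with an estimated correlation). Alas2 was at -0.58 ± 0.13 and Ahsp, which binds alpha globin, at -0.54 ± 0.15. Also at 24 h, of 6 bile duct cell markers, 0 rose and 0 fell at 2000 mg/kg (0 and 0 adjusted over the list alone). Camera on bile duct cell markers gave adjusted p = 0.996 at 2000 mg/kg (adjusted p = 1 with an estimated correlation). Their median was 0.05 and the mean 0.04.

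At 6 h Hmox1 over the vehicle mean ranged from 0.29 to 3.43 at 2000 mg/kg. At 6 h and 1500 mg/kg it was -0.295 in rat 7334 and -0.06 in rat 0644, and up to 3.25 in the others. Rats given the same dose differed widely at 24 h as well. At 1500 mg/kg Hmox1 ranged from -0.38 to 3.49 over the vehicle mean and at 2000 mg/kg from 0.16 to 4.19, while the lowest value over these 12 rats was 2.21 for Mt2A and 2.81 for Akr7a3. For the mean of Hmox1, Atf3 and Hspa1a the SD between rats was 8.46 times that from a rat's 2 arrays, which by itself decides nothing, since rats differ more than repeat arrays for many reasons. Array noise is argued against by the pairing of arrays, since arrays of the same rat lay closer than arrays paired at random (one-sided permutation test, p = 2e-05, with 1e-05 the smallest possible). The shared blank probes are argued against as the whole source, since the smaller SD within rats with or without them was 0.87 times that over all rats, and differences in uptake or injury stay open and untested.

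Vehicle rats differed from the vehicle pool in 3875, 4791 and 2777 gene rows at 3, 6 and 24 h with limma, and 1983 differed at all 3 times, 1983 of them with the same sign. The shared blank probes are argued against, since among vehicle rats without them the lowest correlation of 2 times was 0.639, across genes, which are not independent replicates. A test set beforehand for dye bias gave -0.191, the sign it named for dye bias, but the dye term gives that sign whatever made the offset, which was realised only after the value was seen. A dye effect equal on both arrays of a rat cancels in their mean, so the design argues against it, and one that varied from array to array is argued against by the 1983 rows with 1 sign at 3 times. No value speaks for one that differed between the 2 orientations alike in all rats, and none excludes it, since it would add the same offset as a pool unlike these rats, and differences between rats of the same time do not contain the offset.

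Chance can be excluded, by 100 splits of the same rats with the real one included, for 1500 and 2000 mg/kg against vehicle at each time and for 1500 against 150 mg/kg. At 3 h the real and highest other counts were 1108 and 670 at 1500 mg/kg and 1710 and 628 at 2000 mg/kg. At 6 h they were 1305 and 1701 and 2115 and 1008, and at 24 h 4083 and 4303 and 4608 and 3355. For 1500 against 150 mg/kg they were 793 and 254 at 3 h, 1001 and 96 at 6 h and 3704 and 3625 at 24 h. The number of splits with as many rows was 2 for 1500 mg/kg against vehicle at 6 h and at 24 h, and 1 for the others. The 6 h split with more rows exchanged rat 7334 with vehicle rat 1871. The 24 h split with more rows amounts to exchanging rat 0504 with vehicle rat 5999. Hmox1 of rat 0504 was at -0.38 at 24 h.

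At 150 mg/kg 100 of 100 splits gave at least the 0 rows found at each time, which a count of 0 fixes beforehand, so the splits decide nothing there. The highest others were 96, 1 and 9 at 3, 6 and 24 h. For 2000 against 1500 mg/kg at 24 h the 100 splits with as many rows decide nothing for the same reason, with real and highest other counts of 0 and 3824. For 2000 against 1500 mg/kg at 3 and 6 h chance cannot be excluded, as 7 and 11 splits gave as many rows, with real and highest other counts of 2 and 6 and 1 and 30. The 3824 rows came from 1 split, while the median of the other splits was 2. Whether the high-dose rats of 24 h hold a structure that does not follow the dose was not tested.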
